A study of Homo sapiens with 12 samples.

How the data were processed

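Small RNA was sequenced from human sural nerve, a sensory nerve of the lower leg, in 12 samples: 6 from a control group and 6 from a group labelled DPN. The series' design describes these as individuals without and with DPN. Per the labels, RNA was extracted with a Qiagen miRNeasy Micro kit, libraries were made with a Nextflex small RNA kit and sequenced on a NovaSeq X, and all samples were placed in 1 batch. The nerves of the 2 groups came from different kinds of operation, so the source of the tissue and the group cannot be told apart. Different patients gave the 2 groups, and replicate numbers do not pair samples.

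The authors deposited, for each sample, whole-number read counts per mature miRNA, with 2652 miRNAs and 5 classes of reads that were given to no miRNA. The names of these classes are those that htseq-count writes. The build was GRCh38.p13, per the submitters' processing notes, and the aligner, the miRNA annotation and their versions are not given in the sources used here. Reads that aligned to more than 1 place were kept in a class of their own and made up 35.2% to 46.5% of all counted classes per library. Mature miRNAs made from several hairpin copies, such as miR-138-5p, miR-199a, miR-194-5p and miR-486, may be undercounted for this reason and their levels are uncertain. Reads in no feature made up 2.49% to 5.95%, and the miRNAs themselves 51.0% to 61.4%. These classes stayed out of library sizes and tests.

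The authors also deposited a table of normalized counts, a signal obtained by dividing each library's counts by 1 factor. Its 12 divisors equalled the median of ratios to the geometric mean, within a tolerance of 0.0001. Of its columns, 7 matched the count file of the same number, and 5 control columns matched the count file of another control number. The group of each column was unaffected, and the table was used for an alternative only.

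Totals ran from 7641128 to 41747654 counts, and a floor of 3 counts lay between 0.0719 and 0.393 CPM (counts scaled to a fixed library total). The reads carry no molecular identifiers that were used here, so floors cover counting error only. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 775. Except for the camera test of lists described below, the p-values measure the spread between these samples. That test sets a list's members against the other tested miRNAs, with a preset correlation between members.

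Counts were tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, two-sided, with TMM scaling, robust fits, filterByExpr at its defaults (a count of 10 and a total of 15) and Benjamini-Hochberg adjusted p under 0.05. Fold changes are log2 of DPN over control, given with their standard error (SE). CPM values use the TMM-scaled library sizes. For 21 lists of miRNAs, camera of limma 3.58.1 was run on log2 CPM (prior count 2) with a preset correlation of 0.01, two-sided and adjusted over the lists. The lists covered myelinating glia, neuron, the miR-183 cluster, nerve injury, endothelium, smooth muscle, skeletal muscle, red cell, leukocyte, inflammatory response, miR-199 and miR-214, miR-29, hypoxia, let-7, miR-17-92, epithelium, liver and gut, miR-30, miR-34, HOX cluster and 14q32. Composition measures and principal component 1 were compared by exact permutation tests over all 924 arrangements of the 12 samples, two-sided, whose smallest p is 0.00216. In 5 rounds of simulated counts for these 745 miRNAs, with 200 changed per round, 49.3% of 2-fold and 95.8% of 4-fold changes were recovered and 3.91% of calls were false. The simulated miRNAs varied independently, and as many were raised as lowered. Members of some lists were correlated in these data, with estimates of 0.52 for red cell and 0.78 for the miR-183 cluster. The simulated rates therefore need not hold here.

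The lists, the tests and the rule for named miRNAs were fixed before the data were examined. The rule names the 12 largest called changes in each direction among miRNAs with a mean CPM of at least 10, the 10 most abundant miRNAs and up to 4 members per list with the smallest p. Values are given in the text for part of these miRNAs, and 1 of the largest rises is not reported here. miR-150-5p, miR-150-3p, miR-342-3p, miR-15b-5p, miR-497-5p, miR-195-5p, miR-224-3p, miR-452-5p, miR-1247-3p, miR-138-1-3p and miR-138-2-3p were named after their values were seen. Hairpin positions and host genes were taken from GENCODE 29 on GRCh38, where 735 of the 745 tested miRNAs matched a hairpin gene and 698 had 1 copy. The alternatives were other scalings, filters and tests (DESeq2 1.42.0, limma-voom, limma on the normalized table with a pseudocount of 1 or 0.5), the replicate number as a block, a surrogate variable (sva 3.50.0) and each sample left out in turn. Another 6 alternatives were chosen after seeing the data, and are named as such with their effect.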

Results

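Mature miRNAs were counted in sural nerve from 6 control and 6 DPN samples. Library totals were 7641128 to 36889903 counts in control and 9564040 to 41747654 in DPN, with means of 18162834 ± 10492971 and 25665684 ± 11839680 (SD, n = 6 each, exact permutation p = 0.268). Between 1156 and 1327 miRNAs were detected per control library and 1090 to 1305 per DPN library. The most abundant miRNAs were miR-23a-3p at 96209 CPM over all libraries, miR-23b-3p at 90217, miR-143-3p at 83813, miR-126-3p at 56869, miR-99a-5p at 52670, miR-451a at 50742, miR-145-5p at 47573, miR-223-3p at 35869, let-7b-5p at 35137 and miR-21-5p at 33949. Together these 10 held 58.1% of the mean CPM, and 4 of them (miR-126-3p, miR-451a, miR-223-3p and miR-21-5p) passed the test between groups. This ranking leaves out reads that aligned to more than 1 place, so miRNAs from several hairpins may rank too low. It also pools the groups: miR-451a had 96784 CPM in control and 4699 in DPN, and miR-223-3p 69263 and 2474.

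The comparison of DPN with control asks which miRNAs differ between nerves of individuals with and without DPN. In DPN nerves miR-223-3p, a miRNA of myeloid cells, fell by 4.81 on the log2 scale (SE 0.44), and miR-451a, the main miRNA of red cells, by 4.36 (SE 0.81, n = 6 each). All 4 members of the miR-183 cluster and 9 of 12 of the miR-17-92 family fell (adjusted p = 0.247 and 0.314 for these lists with an estimated correlation). Of 5 tested miRNAs of myelinating glia, miR-204-5p and miR-138-5p fell and miR-211-5p rose, and that list did not pass. miR-21-5p, induced by injury and inflammation, rose by 1.87 (SE 0.37), and miR-146b-5p, an inflammation-responsive miRNA, rose by 2.15 (SE 0.43). Of the fibroblast-enriched miR-199 and miR-214 group 3 of 5 members rose, and of the imprinted 14q32 cluster 8 of 54 (adjusted p = 0.129 and 0.402 for these lists with an estimated correlation). Of 745 miRNAs tested by edgeR's quasi-likelihood test, 143 passed a Benjamini-Hochberg adjusted p of 0.05, 48 higher and 95 lower in DPN. When 1 library was left out, 24 to 70 were higher and 81 to 112 lower. Among miRNAs with a mean CPM of at least 10, 38 were higher and 50 lower, and 24 and 88 of the calls exceeded a 2-fold change. The ranges of the groups did not overlap for 64 of the 745 tested, where chance gives 0.216%, and 62 of these were called. With upper-quartile scaling, which moved the median of all miRNAs up by 0.15, the split was 80 higher and 82 lower. With a red cell score and a miR-223/miR-142 score as covariates, chosen after seeing the data, 1 of the 143 calls was left, miR-223-3p, which is itself part of a score. The scores together accounted for 90.3% of the variance of the group variable.

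The libraries parted by group along principal component 1, which held 37.6% of the variance. Control libraries scored -13.3 ± 2.80 and DPN libraries 13.3 ± 4.25 (SD, n = 6 each), a difference of 26.6 (exact permutation p = 0.00216, the smallest possible).

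**Figure D1:**
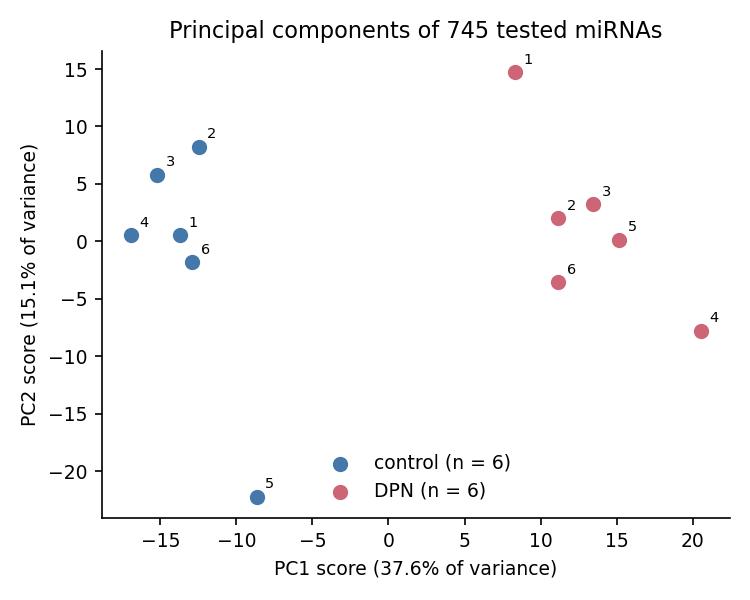
Scores of the 12 libraries on principal components 1 and 2 of log2 CPM, with 1 point per library, numbered by replicate and coloured by group. Control libraries lie between -16.9 and -8.67 on component 1 and DPN libraries between 8.30 and 20.6.

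All 6 members of the red cell list fell in DPN nerves, adjusted over all miRNAs and adjusted over the list alone, with a median log2 fold change of -3.60 (camera adjusted p = 1.56e-05, adjusted p = 0.177 with an estimated correlation). miR-451a went from 96784 ± 107649 to 4699 ± 4050 CPM (edgeR adjusted p = 0.00205), and miR-144-5p and miR-144-3p, made from the neighbouring hairpin, fell by 5.22 (SE 0.93) and 4.50 (SE 0.85). MIR451A lies at 28861369 to 28861440 and MIR144 at 28861533 to 28861618 on chromosome 17 of GRCh38, both on the minus strand within an exon of a long non-coding RNA. Red cell miRNAs held 9.87% ± 10.6 of control counts, from 2.60% to 27.3%, and 0.653% ± 0.458 of DPN counts (exact permutation p = 0.00216, adjusted p = 0.0130). Control replicates 4 and 6, at 18.9% and 27.3%, carried the control mean, with the other controls at 2.60% to 3.50%. When 1 library was left out, the difference ran from -10.7 to -5.74 percentage points. Leaving out any 1 DPN library ended that call, with adjusted p up to 0.136, while leaving out any 1 control did not. The groups did not overlap, with the highest DPN library at 1.52% and the lowest control at 2.60%. A lost call thus does not mean that 1 DPN library carried the fall.

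In the leukocyte list 4 of 7 members fell and none rose, adjusted over all miRNAs. Adjusted over the list alone 4 fell and 1 rose. The median was -2.46 (camera adjusted p = 0.0385, adjusted p = 0.331 with an estimated correlation). miR-223-3p went from 69263 ± 46199 to 2474 ± 785 CPM (edgeR adjusted p = 4.50e-06), its other arm miR-223-5p fell by 4.11 (SE 0.49), miR-142-5p by 2.46 (SE 0.30) and miR-142-3p by 3.03 (SE 0.71). MIR223 lies on chromosome X at 66018870 to 66018979. The lymphocyte members did not follow: miR-150-5p had a log2 fold change of 0.58 (edgeR adjusted p = 0.0506) and miR-342-3p of 0.29 (0.436). When 1 library was left out, miR-150-5p ran from 0.36 to 0.64 and was called without DPN replicates 1 and 6 (lowest adjusted p 0.0361), and miR-342-3p ran from 0.16 to 0.55 and was called without control replicate 5 (0.0391). Leukocyte miRNAs held 7.42% ± 4.70 of control and 0.593% ± 0.174 of DPN counts, a measure added after seeing the data (exact permutation p = 0.00216, adjusted p = 0.00433 over 4 added measures, and up to 0.0173 when 1 library was left out). Most of this share in control was miR-223-3p, at 69263 CPM. Here and below, the leukocyte share therefore does not stand for leukocytes in general. The list's call ended without control replicate 5 (adjusted p = 0.0544) and without DPN replicates 1, 2 and 4 (0.0589, 0.0650 and 0.0591).

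The miR-183 cluster, known from sensory organs and sensory neurons, fell in all 4 members, adjusted over all miRNAs and adjusted over the list alone, with a median of -3.02 (camera adjusted p = 0.000371, adjusted p = 0.247 with an estimated correlation). miR-182-5p went from 1154 ± 526 to 123 ± 111 CPM, miR-96-5p from 231 ± 129 to 22.0 ± 22.9 and miR-183-5p from 363 ± 204 to 51.4 ± 51.0. Their log2 fold changes were -3.22 (SE 0.63), -3.39 (SE 0.55) and -2.82 (SE 0.58), with edgeR adjusted p of 0.00266, 0.000702 and 0.00330. The 3 hairpins lie on the minus strand of chromosome 7, MIR182 at 129770383 to 129770492, MIR96 at 129774692 to 129774769 and MIR183 at 129774905 to 129775014, with no host gene in the annotation. The cluster's share of counts was 0.171% ± 0.0687 in control and 0.0200% ± 0.0168 in DPN, lower in the same group as the red cell and leukocyte shares above. The call of miR-183-3p ended without control replicate 5 and without DPN replicate 3 (adjusted p up to 0.0562).

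Of the 12 members of the proliferation-associated miR-17-92 family, 9 fell adjusted over all miRNAs and 11 adjusted over the list alone, with a median of -1.12 (camera adjusted p = 1.56e-05, adjusted p = 0.314 with an estimated correlation). miR-25-3p, in an intron of MCM7 on chromosome 7, went from 10930 ± 2406 to 5524 ± 705 CPM, and miR-93-5p fell by 1.22 (SE 0.23), miR-18a-5p by 1.75 (SE 0.33) and miR-18b-5p by 1.81 (SE 0.39). The red cell and leukocyte shares fell in the same libraries. With the blood scores as covariates the median of this family was 0.48 (camera adjusted p = 0.897). Its sign decides nothing, since the median SE went from 0.35 to 1.09 in that fit. miR-15b-3p and miR-16-2-3p, from neighbouring hairpins in an intron of SMC4 on chromosome 3, fell by 2.30 (SE 0.37) and 2.46 (SE 0.45), and miR-15b-5p went from 22828 to 6922 CPM.

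In the myelinating glia list 2 of 5 tested members fell and 1 rose, adjusted over all miRNAs, and 3 fell and 1 rose adjusted over the list alone. The list as a whole did not pass (median -0.62, camera adjusted p = 0.286). miR-204-5p, in an intron of TRPM3 on chromosome 9, went from 3927 ± 648 to 1736 ± 889 CPM (edgeR adjusted p = 0.0162). miR-138-5p went from 712 ± 141 to 294 ± 236 CPM (0.0428), and the 3p arms that tell its 2 hairpins apart, miR-138-1-3p and miR-138-2-3p, fell by 1.76 and 2.83. miR-211-5p rose by 1.39 (SE 0.38), from 0.803 to 2.04 CPM, and miR-338-5p had a log2 fold change of -0.62 (0.121). The call of miR-138-5p ended without any 1 of control replicates 1 and 3 and DPN replicates 3 and 5, that of miR-138-1-3p without any 1 of control replicates 3 and 6 and DPN replicates 3 and 5 (adjusted p up to 0.0735 for both), and that of miR-211-5p without DPN replicate 5 (0.0566). Of the 10 tested neuron miRNAs 0 passed by edgeR, DESeq2 or limma-voom, 0 had an unadjusted p under 0.05, and the list did not pass (median -0.05, camera adjusted p = 0.785).

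**Figure D2:**
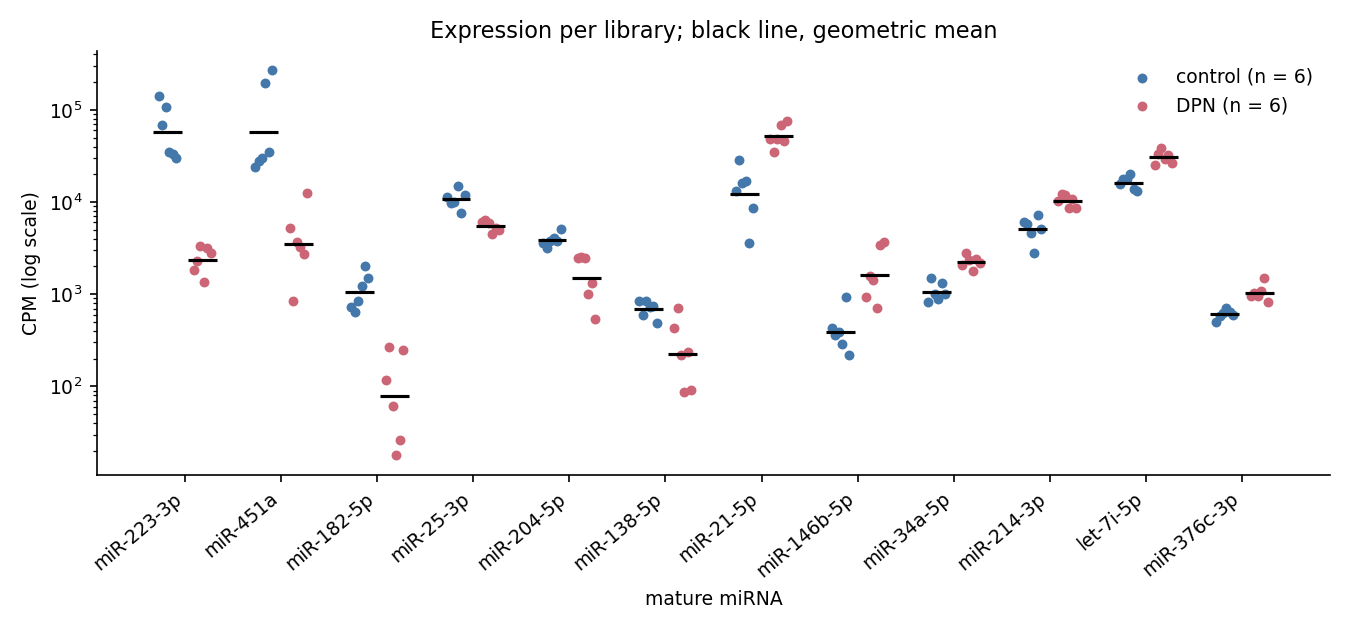
CPM on a log axis for 12 named miRNAs in each library, with 6 control and 6 DPN points and a black line at the geometric mean of each group. miR-223-3p, miR-451a and miR-182-5p lie lower in every DPN library than in any control library, and miR-21-5p and miR-34a-5p lie higher.

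In the list of inflammation-responsive miRNAs 3 of 6 members rose, both over all miRNAs and adjusted over the list alone, with a median of 0.80 (camera adjusted p = 0.0107, adjusted p = 0.177 with an estimated correlation). miR-21-5p, in an exon of VMP1 at 59841266 to 59841337 on chromosome 17, went from 14560 ± 8585 to 53338 ± 15033 CPM (edgeR adjusted p = 0.00228). miR-146b-5p went from 438 ± 258 to 1949 ± 1270 CPM (0.00245) and miR-146a-5p from 831 ± 311 to 1501 ± 359 (0.0211). miR-155-5p had a log2 fold change of 0.76 and did not pass (0.121). The call of miR-146a-5p held in 5 of 12 fits that left out 1 library, with adjusted p up to 0.0667. Red cell and leukocyte shares moved the other way in the same libraries.

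In the list of miR-199 and miR-214 3 of 5 tested members rose adjusted over all miRNAs and 5 adjusted over the list alone, with a median of 0.90 (camera adjusted p = 0.00313, adjusted p = 0.129 with an estimated correlation). miR-214-3p, in an exon of DNM3OS on chromosome 1, went from 5254 ± 1486 to 10382 ± 1580 CPM (edgeR adjusted p = 0.00410). miR-199a-3p rose by 0.81 (SE 0.21) and miR-199a-5p by 1.23 (SE 0.35), both with uncertain levels since several hairpins make them. The call of miR-199a-3p ended without DPN replicates 3 and 5 (up to 0.0653), and that of miR-199a-5p held in 7 of 12 such fits. In the same libraries the red cell share was 9.87% in control and 0.653% in DPN, and the leukocyte share 7.42% and 0.593%.

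Of the 54 tested miRNAs of the 14q32 cluster 8 rose and none fell, over all miRNAs and adjusted over the list alone, and 44 had a positive log2 fold change. The median was 0.26 (camera adjusted p = 0.00313, adjusted p = 0.402 with an estimated correlation). The list did not pass fry's directional test either (adjusted p = 0.0760). miR-381-3p rose by 1.17 (SE 0.23), miR-431-5p by 1.06 (SE 0.30), miR-370-3p by 0.89 (SE 0.23) and miR-376c-3p by 0.80 (SE 0.18). miR-431-5p lost its call without DPN replicate 3 (edgeR adjusted p = 0.0583). The red cell and leukocyte shares were lower in the same DPN libraries, at 0.653% and 0.593%, than in control, at 9.87% and 7.42%.

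Other large rises were in miR-1247-5p, in an exon of DIO3OS, from 116 ± 48.0 to 373 ± 196 CPM, and in miR-511-5p, in an intron of the macrophage mannose receptor gene MRC1, from 11.9 ± 4.46 to 39.0 ± 13.2 CPM. miR-483-5p, in an intron of IGF2, rose by 1.41 (SE 0.37) and miR-195-3p by 1.20 (SE 0.24). miR-335-3p, in an intron of MEST, rose by 1.60 (SE 0.46), and miR-675-3p and miR-675-5p, from an exon of H19, by 1.17 (SE 0.34) and 1.14 (SE 0.38). These last 3 held their call in 7, 9 and 4 of 12 fits that left out 1 library. miR-34a-5p, a p53-responsive miRNA, went from 1090 ± 262 to 2271 ± 327 CPM, 1 of 5 members of its family to pass (camera adjusted p = 0.0556, and 0.0112 without control replicate 2 and 0.0464 without DPN replicate 5). let-7i-5p went from 16440 ± 2720 to 30852 ± 5063 CPM, the 1 call among 9 let-7 members, whose median of 0.03 changed sign with another scaling.

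**Figure D3:**
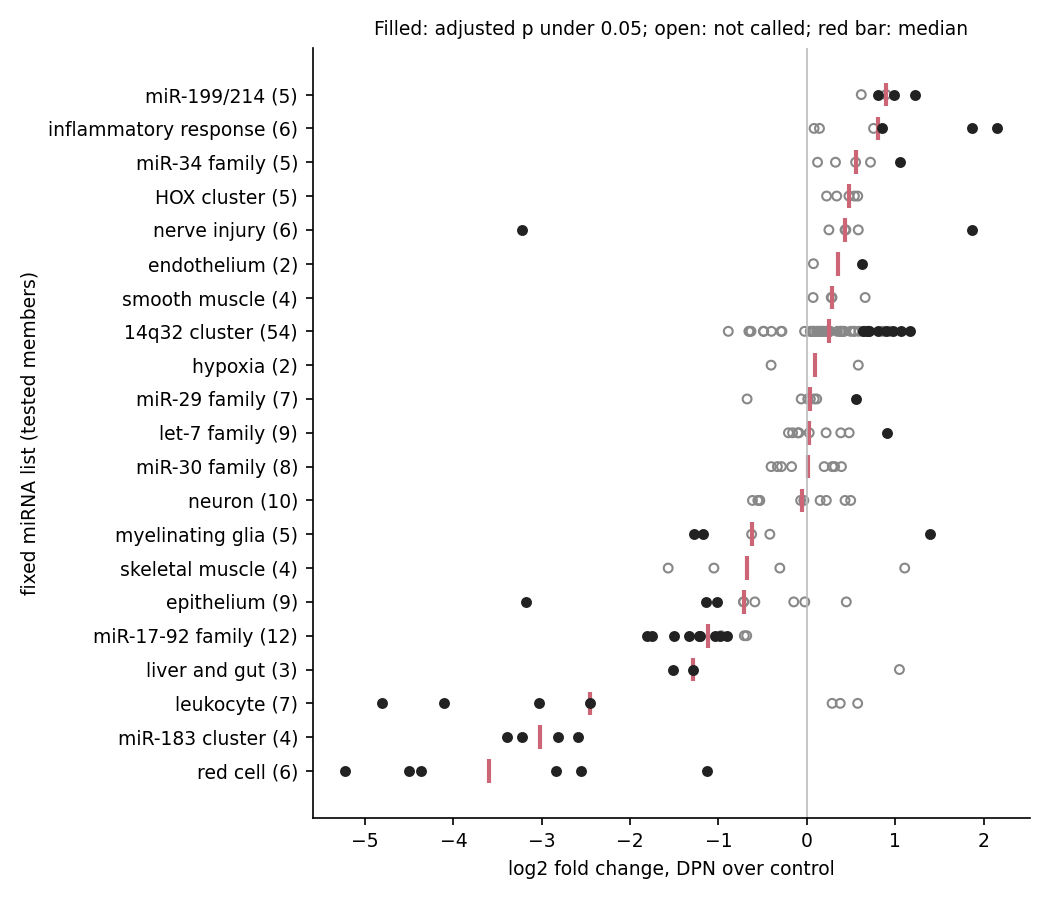
Log2 fold changes of DPN over control for the tested members of the 21 lists, 1 point per miRNA, filled where the edgeR adjusted p was under 0.05 and open otherwise, with a red bar at the list's median. The red cell, miR-183 and miR-17-92 lists have every member below 0.

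In the epithelium list 3 of 9 members fell over all miRNAs and 4 adjusted over the list alone, with a median of -0.72 that did not pass (camera adjusted p = 0.0514). The list passed without control replicates 4 and 5 and without DPN replicates 1 and 3, each left out alone (0.0360, 0.0322, 0.0246 and 0.0173). miR-205-5p, a keratinocyte miRNA, went from 8.60 ± 5.53 to 0.900 ± 1.18 CPM, and miR-200c-3p from 43.2 ± 14.1 to 21.4 ± 4.19. The list's share of counts was 0.0137% ± 0.00244 in control and 0.00865% ± 0.00291 in DPN (exact permutation p = 0.0130, adjusted p = 0.0390), a call that held in 3 of 12 fits that left out 1 library. The red cell and leukocyte shares, 9.87% and 7.42% in control, were also lower in DPN, at 0.653% and 0.593%. With the blood scores as covariates the epithelium median was 1.11 (camera adjusted p = 0.185), in a fit whose median SE was 1.09 against 0.35. The liver and gut list had been fixed as a negative control, for tissue absent from a nerve biopsy. Of its members, miR-194-5p fell by 1.52 and miR-192-5p by 1.29 (edgeR adjusted p = 0.000702 and 0.00231). Both calls held in all 12 fits that left out 1 library. The list did not pass by camera (adjusted p = 0.304, 2 lower and 1 higher of 3 adjusted over the list alone), but for these 2 members the control failed. By fry's directional test the list passed as lower in DPN (adjusted p = 0.00333), so by that test the control failed as a list. The endothelial miR-126-3p rose from 44758 ± 7000 to 68980 ± 14404 CPM (edgeR adjusted p = 0.0269), a call that held in 2 of 12 such fits (adjusted p up to 0.118). miR-29a-3p rose by 0.56 (0.0497), a call that held in 1 of 12 (up to 0.145), and adjusted over the list alone no miR-29 member passed. The lists of nerve injury (camera adjusted p = 0.245), endothelium (0.340), smooth muscle (0.611), skeletal muscle (0.496), miR-29 (0.611), hypoxia (0.697), let-7 (0.399), miR-30 (0.869) and HOX cluster (0.0815, and 0.0171 without control replicate 5) did not pass. By edgeR 0 members of the smooth muscle, skeletal muscle, hypoxia, miR-30 and HOX cluster lists passed, with 0, 1, 1, 0 and 2 at an unadjusted p under 0.05, while DESeq2 called 0, 1, 0, 0 and 1 and limma-voom 0, 0, 1, 2 and 2. Adjusted over the list alone, 3 nerve injury members rose and 1 fell, and 1 member rose in each of the endothelium, let-7 and miR-34 lists.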

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

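For 9 measures, each in 1 group of 6 libraries, the highest or lowest library stood far from the others relative to the group's range. As 107 measures were looked at in each of the 2 groups and chance does so in about 1 in 20, about 10.7 would be met by chance. In the DPN group, replicate 1 had the lowest miR-126-3p, at 42987 CPM against 67759 to 86082 in the others. The same library had the highest miR-132-3p at 736 CPM (491 to 556 in the others), the highest miR-30e-3p at 1310 (600 to 747) and the highest miR-34c-5p at 164 (59.2 to 85.2). DPN replicate 4 had the highest miR-30d-5p, at 5310 CPM against 2241 to 2895, and DPN replicate 6 the lowest miR-497-5p, at 2980 against 3988 to 4653. Control replicate 5 had the lowest miR-30e-5p, at 288 CPM against 564 to 719, and the highest miR-615-3p, at 271 against 88.6 to 126. Control replicate 4 had the highest share of skeletal muscle miRNAs, 0.00856% against 0.00299% to 0.00471%.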

How the results depend on the processing

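The alternatives without control replicates 4 and 6 (highest in miR-451a), with scaling without the blood lists, with the table's control numbers as a block, with 1-hairpin miRNAs alone, with thinned libraries and with blood scores as covariates were chosen after seeing the data. Against 143 calls, 48 higher and 95 lower, at least 110 were made when any 1 library was left out (24 to 70 higher and 81 to 112 lower), and 87 of the 143 were called in each of these fits. The higher calls numbered 31 without control replicate 1, 31 without control replicate 4, 27 without DPN replicate 3 and 24 without DPN replicate 5. They numbered 80 with upper-quartile factors, 31 with the filter of 10 CPM, which tests fewer miRNAs, 101 of 229 calls with limma-voom, 29 without control replicates 4 and 6 and 29 after thinning. With the blood scores as covariates 2 calls were made, 1 higher and 1 lower, both of miRNAs that are part of a score and are thus fitted against themselves. Of the 143 calls 1 was left, miR-223-3p, and miR-142-3p turned from lower to higher. That fit called 3 lists, the inflammatory response and 14q32 lists as before and the smooth muscle list, which had not been called. DESeq2 made 173 calls, among them all 143. The replicate numbers do not pair the samples: correlations of same-numbered libraries ran from -0.14 to 0.20, and 1 of 6 correlated best with its own number. As a replicate block they gave 115 calls, 107 of them shared, and with the authors' table's numbers they gave 92 calls, 23 higher. The 7 lists called became 0 with an estimated correlation and 11 by fry's directional test, and 6 to 8 when 1 library was left out. By fry's directional test the 14q32 list lost its call (adjusted p = 0.0760). The lists it added were nerve injury (0.0227), epithelium (0.0273), liver and gut (0.00333), miR-34 (0.0201) and HOX cluster (0.0153). Of the 6 planned composition measures 2 were called, which became 0 without each library's most abundant miRNA, and 0 to 2 when 1 library was left out. In control replicates 4 and 6 the most abundant miRNA was miR-451a itself, at 194030 and 270277 CPM. Taking it out removes the red cell signal there, so that setting does not test the red cell call. The difference on principal component 1 stayed between 26.8 and 28.7 when 1 library was left out. Of 3069 alternative values for named miRNAs, 185 called ones lost and 54 uncalled ones gained the call, and 76 reversed, 10 of these called and all 10 with the blood scores. Except for the covariate fit, where the cause lies in part in the larger SE, the cause was not tested.

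With RLE factors, values reversed for the let-7 family list -0.0092 and the miR-30 family list -0.012. With a filter of 10 CPM in 6 samples, values reversed for miR-23b-3p -0.064, miR-99a-5p -0.054, miR-126-5p -0.044, miR-29c-3p -0.021, the miR-29 family list -0.066 and the let-7 family list -0.094. With limma-voom, values reversed for miR-99a-5p -0.092 and miR-126-5p -0.035. In the authors' normalized table with a pseudocount of 1, values reversed for miR-99a-5p -0.13, miR-145-3p -0.00050 and miR-206 -0.11. In that table with a pseudocount of 0.5, values reversed for miR-99a-5p -0.13, miR-145-3p -0.00050 and miR-206 -0.27. With the replicate block, values reversed for miR-99a-5p -0.10 and the miR-30 family list -0.0061. Without control replicates 4 and 6, values reversed for miR-23b-3p -0.085, miR-99a-5p -0.037, miR-126-5p -0.066, miR-145-3p -0.083, miR-133a-3p 0.31, the skeletal muscle list 0.081 and the let-7 family list -0.097. With the blood scores as covariates, of which miR-144 and miR-142 are part, these values reversed: miR-335-3p -0.17, miR-144-5p 0.059, miR-144-3p 2.12, miR-142-3p 4.88, miR-23a-3p -1.17, miR-23b-3p -0.79, miR-143-3p -1.57, miR-99a-5p -0.50, miR-145-5p -3.19, miR-218-5p 1.58, miR-143-5p -1.80 and miR-145-3p -2.43. The same fit also reversed miR-499a-5p 1.46, miR-29c-5p -0.85, miR-210-5p 0.63, let-7e-5p -0.75, let-7d-5p 0.0015, miR-93-5p 0.073, miR-18a-5p 1.08, miR-18b-5p 0.64, miR-205-5p 1.38, miR-200b-3p 0.46, miR-30e-5p 0.75 and miR-30e-3p 0.51. It further reversed miR-30d-5p -1.003, miR-10a-5p -1.06, miR-615-3p -0.58, miR-342-3p -0.52, miR-195-5p -0.40, miR-224-3p -0.18, the neuron list 0.81, the smooth muscle list -2.12, the miR-17-92 family list 0.48, the epithelium list 1.11, the miR-30 family list -0.21 and the HOX cluster list -0.58. With scaling without the blood lists, values reversed for miR-23b-3p -0.0017, the miR-29 family list -0.0083, the let-7 family list -0.037 and the miR-30 family list -0.041. With the block numbered as in the authors' table, values reversed for miR-99a-5p -0.10 and the miR-30 family list -0.0076. With 1-hairpin miRNAs alone, values reversed for the neuron list 0.19 and the skeletal muscle list 0.40. After thinning, values reversed for miR-23b-3p -0.087, miR-99a-5p -0.080, miR-126-5p -0.050, miR-145-3p -0.045, miR-29c-5p -0.0079, miR-29c-3p -0.047, the miR-29 family list -0.12, the hypoxia list -0.078 and the let-7 family list -0.13. When 1 library was left out, values that changed sign ranged as follows: miR-126-5p -0.082 to 0.26, miR-29c-3p -0.058 to 0.23, the neuron list -0.21 to 0.022, the miR-29 family list -0.10 to 0.18, the hypoxia list -0.12 to 0.18, the let-7 family list -0.083 to 0.13 and the miR-30 family list -0.099 to 0.031. The others were miR-23b-3p -0.051 to 0.16, miR-99a-5p -0.20 to 0.22, miR-145-3p -0.30 to 0.33, miR-145-5p -0.19 to 0.67, miR-29c-5p -0.14 to 0.21, the smooth muscle list -0.076 to 0.48 and skeletal muscle share -0.0010 to 8.13e-05.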

Other observations

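Of the 206 hairpins with both arms tested, 166 had arms with log2 fold changes of the same sign and 18 had both arms called, none in opposite directions. Across hairpins, which are not independent, Pearson's r was 0.83 and Spearman's rho 0.71. Among 51 groups of hairpins no more than 10000 bases apart, 13 held at least 2 calls and none held calls in both directions. miR-497-5p and miR-195-5p, from 2 neighbouring hairpins on chromosome 17, rose by 0.93 and 0.67, and miR-224-3p and miR-452-5p, both in exons of GABRE on chromosome X, by 1.03 and 0.91. When 1 library was left out, miR-195-5p kept its call in 8 of 12 fits (edgeR adjusted p up to 0.0646) and miR-452-5p in 6 (up to 0.0606). miR-1247-3p rose by 2.32 and miR-150-3p by 1.09, which lost its call without DPN replicate 3 (0.0540).

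The tests of the counts left by other miRNAs, of a fixed ratio of blood cells, of hairpin copies and of blood scores as covariates were chosen after the result was seen. The red cell miRNAs, miR-223 and miR-142 (10 members) had a median log2 fold change of -3.57. Thinning every library to 7641128 counts left -3.77. Thinning keeps each miRNA's expected share of its library, so this outcome was nearly fixed in advance and decides nothing about library depth. Scaling without the blood lists left -3.63 but moved the median of all miRNAs by only -0.048, so it decides nothing. The counts that the 10 most abundant other miRNAs left for the rest shifted by -0.46 on the log2 scale (SE 0.10, -0.50 to -0.39 when 1 library was left out), which argues against counts taken by these 10 as the whole cause. The counts left include the members' own, so part of this shift follows from their fall. It is also a shift of unscaled shares, set against scaled fold changes. Less whole blood with its cells in 1 fixed ratio is also argued against, since the ratio of miR-223-3p to miR-451a differed 53.1-fold among controls, from 0.111 to 5.87. It differed 32.6-fold without control replicate 1, 32.3-fold without control replicate 6 and 6.19-fold without control replicates 4 and 6. Different amounts of separate blood cells in the tissue, a different operation and a change within the nerve remain open, and the design cannot part them.

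For the miR-183 cluster, the mean log2 CPM over the 6 controls had a Spearman's rho with miR-223-3p of -0.77 (exact permutation p = 0.103; Pearson's r -0.80, p = 0.0847, and -0.98 without the 2 farthest libraries) and with miR-451a of 0.77 (exact permutation p = 0.103, r 0.63 with p = 0.215, and 0.79 without the 2 farthest). None of 4 such relations passed adjustment (lowest adjusted p 0.206 for rho and 0.339 for r). Over the 6 DPN libraries rho was 0.37 with miR-451a and 0.14 with miR-223-3p (exact permutation p = 0.497 and 0.803). With so few libraries these values decide neither whether red cells carry the cluster nor whether cells that hold miR-223 do, and both stay open. Of the 10 tested neuron miRNAs 0 passed by edgeR, DESeq2 or limma-voom and 0 had an unadjusted p under 0.05, with a median log2 fold change of -0.05 and a lowest of -0.62, against -3.02 for the cluster. These members went both ways, and with 1-hairpin miRNAs alone their median was 0.19. Some were scarce, such as miR-9-3p at 0.98 CPM over all libraries, and members from several hairpins may be undercounted. No list was of sensory fibres alone, so a loss of such fibres stays open.

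The 48 miRNAs higher in DPN had a median log2 fold change of 1.00. Scaling without the blood lists left 0.94 but moved the median of all miRNAs by only -0.048, which decides nothing. The counts left by the 10 most abundant other miRNAs shifted by 0.26 (SE 0.085, 0.22 to 0.31 when 1 library was left out), which argues against these as the whole cause and leaves a part open. The counts left here, too, include those of the 48 miRNAs and are unscaled shares. Of the 48 miRNAs 95.8% had 1 hairpin gene, but so had 93.7% of all tested miRNAs, so this share decides nothing about reads shared between copies. Of 100 splits drawn from the 462 possible, 1, the real one, gave as many as 143 calls, the highest other gave 45 and 96 gave none. These draws argue against a random grouping as the source of 143 calls, but not every split was drawn. They cannot part the group from the kind of operation or from the blood cells. With the 2 blood scores as covariates 2 calls were made, both of miRNAs in a score, and 1 of the 143 was left, but the median SE went from 0.35 to 1.09, and different amounts of blood cells in the 2 groups cannot be told apart from the group itself.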
